A study of Mus musculus with 8 samples.

How the data were processed

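RNA from cultured mouse spleen CD8+ dendritic cells was measured on 8 Affymetrix MG-U74Av2 arrays, 2 in each of 4 groups: medium alone at 4 hours, medium alone at 16 hours, IFN-γ at 4 hours and IFN-γ at 16 hours. The groups and the replicate numbers 1 and 2 were taken from the sample titles. Per the labels' protocols, about 10 µg of total RNA was made into biotinylated target for each array.

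The deposited values are intensity summaries per probe set, and RMA is the tool named in the submitters' processing notes, with its version and settings not given in the sources used here. Their range shows that the authors deposited intensity on a linear scale, from 2.65 to 12523.5 over all arrays, so log2 was taken here with no pseudocount and no further normalization. Array scanner files were not used here.

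Of 12488 probe sets, 66 array controls were left out of all tests, which leaves 12422. Gene names came from the platform annotation and were matched by gene number to a RefSeq table of assembly GRCm38.p6: 10833 probe sets had 1 symbol, 396 had several and 1193 were unlisted and are unnamed here. Of the 10833, 10817 matched by gene number, 0 symbols changed and 16 kept the name of the annotation. No coordinates are given, since the array names no genome build. For gene lists and named genes, each of the 8251 genes was represented by its probe set with the highest mean over all 8 arrays. The dimmest probe sets of C1qb, Cd68, Fdps, Lyz2, Mcm5, Samhd1, Tap1 and Tmem37 did not pass where the brightest did.

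Differences were tested on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes, two-sided), in a fit of the 4 group means over all 8 arrays, so that the groups share 1 estimate of the spread per probe set. P-values were adjusted by Benjamini-Hochberg over the 12422 probe sets of each comparison and called at 0.05. Comparisons were IFN-γ against medium at 4 and at 16 hours, the difference between these effects, 16 against 4 hours in medium and in IFN-γ, and the IFN-γ effect in an additive model of time and treatment. There were 18 pathway lists and 10 lists of cell type markers, 28 in all, tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, and adjusted over the lists of a comparison. The interferon-gamma response list holds transcription factors, regulators and targets of the receptor's signalling.

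The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names, at 4 and at 16 hours, the 15 largest rises and 10 largest falls with an adjusted p under 0.05 and both treated arrays beyond both control arrays, and 6 each way for the other comparisons. It adds up to 4 members with the smallest p of each list described, and a fixed set of genes given whether or not they passed, not all of which is reported here.

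Replicate numbers were checked for pairing through the correlation, between groups, of the difference between array 1 and array 2. All 6 correlations lay between 0.367 and 0.740, so the numbers pair the arrays, from the data and not from a label, and values with the replicate number as a block are given beside the results printed where they change a call or move a count by over 1.5 times.

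The statistics were tested on simulated data, with 200 of 12422 probe sets changed by known amounts on arrays with a shared number effect. For the 4-hour comparison, limma without the block recovered 78% of changes of 1 on the log2 scale and 0% of changes of 0.5, with 0 false calls among 135. With the block it recovered 88% of changes of 1, with 10 false calls among 155. For the difference of effects it recovered 10% of changes of 1 without the block, with 1 false call among 90, and 40% with it, with 10 false calls among 129. At 16 hours there was 1 false call among 132 without the block and 14 among 158 with it. The simulated groups had the same spread, unlike the real ones. The SD over probe sets of the difference between replicate arrays was 0.170 in medium and 0.176 with IFN-γ at 4 hours. At 16 hours it was 0.241 and 0.311. The simulation therefore does not show how many false calls a shared estimate of spread gives at 16 hours. Its spread was also taken from the fit without the block, which already holds the number effect, before that effect was added. The number effect is thus counted in both, and the simulated rates may not carry over to these arrays.

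Alternatives were quantile normalization, median centring, leaving out the dimmest 40% of probe sets, a trended and robust prior, a fit of only the 4 arrays compared, the replicate block, each array left out in turn, an adjusted p under 0.01, a log2 difference of at least 1, and 1 mean value per gene. Where an array was left out, the lone array of its group was assumed to vary like those of the other groups. Added after the data had been seen were a fit without both 16-hour arrays of number 1, and one without the 19 probe sets at least 0.5 lower on both arrays of medium at 4 hours than on each other array. Tables were handled in Python 3.11.15 with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.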

Results

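CD8+ dendritic cells, a spleen subset that takes up and presents antigen to T cells, were purified from 60-day-old female DBA/2J mice given 10 µg of Flt3 ligand for 9 days, a growth factor that expands dendritic cells. The cells were cultured in medium alone or with 200 U/ml of mouse interferon gamma (IFN-γ) for 4 or 16 hours, and total RNA was hybridised to Affymetrix mouse expression arrays. The 4 groups held 2 arrays each, 8 in all, and the number of arrays limits the precision. Median intensity over the 12422 probe sets tested lay between 51.3 and 53.7 on the 8 arrays. The median of 15 antisense control probe sets, a measure of unspecific signal, lay between 44.9 and 61.2, and the group means of Clec4a2, Hbb-b2 and Mrc1 were below it. So were those of Cxcl9, Cxcl10, Ubd and Gbp2b in medium, Ikzf1 in medium at 4 hours, and Cnn3 in medium at 16 hours. Also below it were Hspa1b and Spic at 16 hours, Vcan with IFN-γ at 16 hours, and C3ar1 and Vcan in both groups at 4 hours. C1qb and Ccl2 were at this level in medium at 4 hours, Tmem37 in both groups at 4 hours, and Il12b in all 4 groups. The size of the differences of these genes is uncertain. Replicate arrays correlated across probe sets with r = 0.997 and 0.993 in medium at 4 and 16 hours, and 0.996 and 0.989 with IFN-γ. The ratio of 3' to 5' signal of Actb, a measure of RNA and labelling quality, was 2.04 and 2.20 on the arrays of medium at 4 hours, and between 1.47 and 1.68 on the other 6. Nothing in the labels says that the 2 arrays of a group came from separate mice or cultures, so the p-values measure only the spread between these arrays, which may be technical.

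After 4 hours with IFN-γ, the chemokine genes Cxcl9 and Cxcl10 and genes of the interferon-inducible GTPases rose. Cxcl9, which encodes a chemokine that attracts activated T cells, went from a log2 intensity of 5.01 ± 0.11, below the antisense controls, to 9.14 ± 0.17 (SD, n = 2 per group), a log2 difference of 4.13 (SE 0.22, adjusted p = 0.000164, limma with Benjamini-Hochberg adjustment). Cxcl10, a chemokine acting on the same receptor, rose by 2.35 (SE 0.16, adjusted p = 0.000278). Ubd, a ubiquitin-like modifier likewise below these controls in medium, rose by 2.08 (SE 0.17, adjusted p = 0.0011), and Socs1, an inhibitor of cytokine receptor signalling, by 1.39 (SE 0.18, adjusted p = 0.0141). The transcription factor Irf1 rose by 0.84 (SE 0.10, adjusted p = 0.0123), from 10.05 ± 0.04 to 10.88 ± 0.02. Wars, the tryptophanyl-tRNA synthetase, rose by 0.75 on its brightest probe set (SE 0.12, adjusted p = 0.0436). Its next probe sets differed by 1.60 (adjusted p = 0.00439) and 0.55 (adjusted p = 0.139).

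Of 9 measured interferon-inducible GTPases, which act in defence against intracellular pathogens, 7 rose and none fell at 4 hours, and 9 rose when adjusted over the list alone. Iigp1 rose by 2.63 (SE 0.18), Irgm1 by 1.80, Irgm2 by 1.79 and Igtp by 1.63 on the log2 scale. Camera gave this list an adjusted p = 2.05e-46, and adjusted p = 0.0721 with an estimated correlation. Of 15 measured genes on the interferon-gamma response list, 4 rose (5 adjusted over the list alone), namely Cxcl9, Cxcl10, Socs1 and Irf1, with a camera adjusted p = 2.38e-19 and adjusted p = 0.0721 with an estimated correlation. None of 18 measured type I interferon-stimulated genes passed the test over all probe sets, 13 did when adjusted over the list alone, and 9 with the replicate number as a block. Their median log2 difference was 0.48, and camera gave an adjusted p = 1.55e-31, and adjusted p = 0.0721 with an estimated correlation. Among them, Ifit2 differed by 1.09 (adjusted p = 0.0542, or 0.00152 with the block) and Adar by 0.70 (adjusted p = 0.0562, or 0.00451 with the block). Both were also higher at 16 than at 4 hours in medium. Ifit2 went from 6.34 and 6.41 to 7.03 and 7.54 there, and Adar differed by 0.41. Isg15, of the same list, went the other way in medium, from 9.53 and 9.54 to 8.97 and 9.11. Of 18 measured genes of MHC class I presentation, 1 rose, H2-T24 (0.74, adjusted p = 0.0455), which was also 0.92 higher at 16 than at 4 hours in medium, and 2 did when adjusted over the list alone or with the block. The camera adjusted p of this list was 5.05e-06, and adjusted p = 0.196 with an estimated correlation.

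In all, 32 probe sets rose with IFN-γ at 4 hours and 0 fell by limma. The 32 carry 26 distinct gene names. At an unadjusted p under 0.05 by limma, 169 were lower and 330 higher. The fit with the replicate number as a block called 135 higher and 22 lower, and all 32 calls were among them. The other genes with the largest rises were Cnn3, an actin-binding calponin (1.79), Gbp7 (1.62), Gbp2b (1.42), Gbp2 (1.28), Nampt, an enzyme of NAD synthesis (1.02), Ikzf1, a zinc finger transcription factor (0.98), and Mxd1 (0.91). A dimmer probe set of Ikzf1 differed by 0.02, and the called probe set was also 1.28 higher at 16 than at 4 hours in medium, a value looked up after the call was seen. Of the 15 genes named by size of rise, 6 were called whichever array was left out: Cxcl9, Iigp1, Cxcl10, Ubd, Irgm2 and Igtp. The total was 8 without array 1 of medium at 4 hours, 10 without array 2, 9 without either IFN-γ array at 4 hours, 67 without either IFN-γ array at 16 hours, and 93 in a fit of the 4 arrays compared. Actb 3' to 5' ratios differed between the groups of this comparison, at 2.04 and 2.20 in medium and 1.47 and 1.65 with IFN-γ.

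The series concerns dendritic cells competent for indoleamine 2,3-dioxygenase, the enzyme that begins tryptophan breakdown and is encoded by Ido1. The brighter of its probe sets read 5.67 ± 0.00 in medium and 5.59 ± 0.04 with IFN-γ at 4 hours, a log2 difference of -0.08 (SE 0.15) with an adjusted p of 1. Its group means, 48.2 to 58.1 in intensity, were at the level of the antisense controls and those of the dimmer probe set were below it, so whether Ido1 changed cannot be read from either. At 16 hours it differed by -0.02. With 1 mean value per gene, which averages it with the dimmer probe set, the 4-hour difference of Ido1 was 0.32, with an adjusted p of 1. The dimmer probe set of Ido1, at 3.99 ± 0.03 in medium and 4.70 ± 0.03 with IFN-γ at 4 hours, differed by 0.71 at 4 hours (SE 0.12, adjusted p = 0.0518) and by 0.03 at 16 hours. It was also 0.36 higher at 16 than at 4 hours in medium (adjusted p = 0.14, or 0.0362 with the block). With the replicate number as a block, the 4-hour difference of this probe set passed the test (adjusted p = 0.00511), as it did without either IFN-γ array at 16 hours (adjusted p = 0.0203). Over the alternatives its adjusted p ran from 0.00511 to 0.575. Of 9 measured genes of tryptophan metabolism, 1 rose at 4 hours, Wars, and 1 when adjusted over the list alone, and the list had a camera adjusted p of 0.995, with a median of -0.06 and a mean of 0.03. Tyrobp, which encodes the adaptor DAP12 and was chosen from prior knowledge of the study, differed by -0.47 at 4 hours (SE 0.12, adjusted p = 0.308) and -0.41 at 16 hours (adjusted p = 0.717).

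Genes of costimulation and of the receptor for IFN-γ did not pass the test at 4 hours. Cd40 differed by 0.66 (adjusted p = 0.116, or 0.0229 with the block) and Cd86 by 0.50 (adjusted p = 0.601, or 0.0287 with the block). Cd80, Il12b, Ifngr1, Ifngr2 and Socs3 differed by 0.34, -0.08, 0.09, -0.01 and 0.32. Il12b was at the level of the antisense controls, so whether it changed cannot be read. The markers of the sorted cell, Cd8a and Itgax, differed by 0.14 and -0.23. Irf8, a transcription factor of this dendritic cell subset, differed by 0.61 at 4 hours (adjusted p = 0.0612, or 0.00892 with the block).

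At 16 hours, Cxcl9, Socs1, Irf1 and 5 of 9 interferon-inducible GTPases were higher with IFN-γ, and Ccl9, Cd14 and C3ar1 were lower. Cxcl9 rose by 3.40 (SE 0.22, adjusted p = 0.000313), again from below the antisense controls, Iigp1 by 2.08 (SE 0.18, adjusted p = 0.00197), Socs1 by 1.51 (SE 0.18, adjusted p = 0.0137) and Irf1 by 0.96 (SE 0.10, adjusted p = 0.0075). Irf8 rose by 0.82 (SE 0.10, adjusted p = 0.0158) and Tap1, a subunit of the peptide transporter of MHC class I presentation, by 0.80 (SE 0.13, adjusted p = 0.0499). Ccl9, a chemokine, fell by 1.83 (SE 0.11, adjusted p = 0.0002), from 8.51 ± 0.05 to 6.67 ± 0.03. Falls here are against medium at the same time. Ccl9 rose with time in medium, from 7.11 and 7.18 on the arrays at 4 hours. With IFN-γ it read 6.53 and 6.69 at 4 hours and 6.69 and 6.65 at 16 hours, so it showed no such rise. Cd14, the co-receptor for lipopolysaccharide, fell by 1.08 (SE 0.13, adjusted p = 0.0137), and C3ar1, the receptor for the complement fragment C3a, fell by 0.96 (SE 0.12, adjusted p = 0.0166). Cd14 was level with time in medium, while C3ar1 rose from 5.41 and 5.56 to 6.82 and 7.07. With IFN-γ, C3ar1 rose less, from 5.13 and 5.10 to 5.95 and 6.02.

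**Figure D1:**
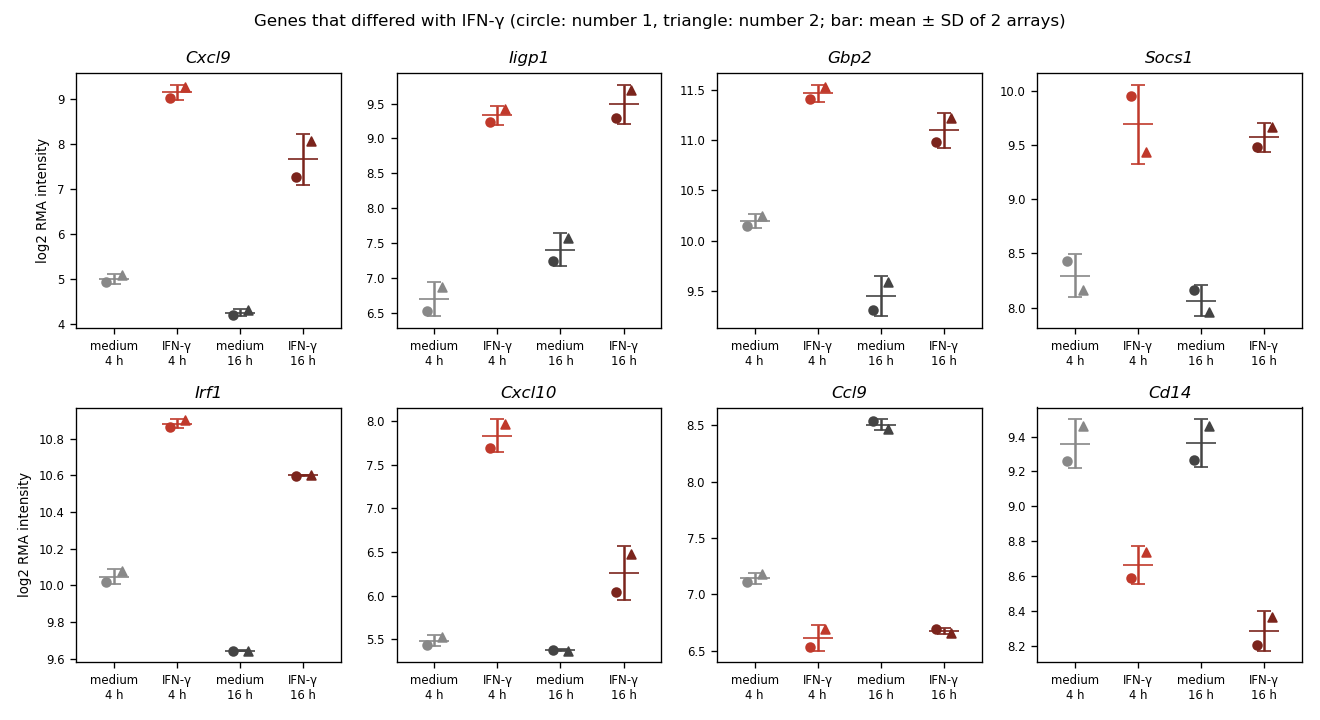
Log2 RMA intensity (vertical axis, a separate range for each gene) of 8 genes in the 4 groups, with a point per array, a bar at the mean and whiskers of 1 SD (n = 2). Cxcl9 read 9.14 with IFN-γ and 5.01 in medium at 4 hours, and Ccl9 read 6.67 with IFN-γ and 8.51 in medium at 16 hours.

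Of 9 measured interferon-inducible GTPases, 5 rose at 16 hours (9 adjusted over the list alone, and 9 with the block), with a camera adjusted p = 2.1e-39 and adjusted p = 0.0708 with an estimated correlation. They were led by Iigp1, Gbp2 (1.65), Igtp (1.46) and Gbp7 (1.45). On the interferon-gamma response list 4 of 15 rose (5 adjusted over the list alone), with a camera adjusted p = 1.38e-14 and adjusted p = 0.0708 with an estimated correlation. Of the type I interferon-stimulated genes 0 of 18 passed, over all probe sets or adjusted over the list alone, with a median of 0.20, and camera gave adjusted p = 3.93e-05 and adjusted p = 0.422 with an estimated correlation. Of MHC class I presentation 1 of 18 rose, Tap1, and 6 did when adjusted over the list alone, or 3 with the block (camera adjusted p = 2.07e-07, and adjusted p = 0.173 with an estimated correlation). Among pattern recognition and uptake receptors 2 of 18 fell, Cd14 and Clec4a2 (-0.92), and 4 did when adjusted over the list alone or with the block, with a camera adjusted p = 7.39e-05 and adjusted p = 0.276 with an estimated correlation. None of 12 macrophage markers passed over all probe sets by limma without the block, and 4 fell when adjusted over the list alone. With the block 2 fell, Spic (-0.96, adjusted p = 0.0049) and Mrc1, which was below the level of the antisense controls. Their median was -0.25, and camera gave an adjusted p = 1.32e-07, and adjusted p = 0.0708 with an estimated correlation.

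In all, 20 probe sets rose and 12 fell at 16 hours, and the fit with the replicate number as a block called 51 higher and 54 lower, all 32 calls among them. Further rises were those of Cnn3 (1.63), Gbp2b (1.44), Ubd (1.16), Il18bp, which encodes a protein that binds interleukin 18 (1.01), Samhd1 (0.84) and Ppa1 (0.74). Further falls were those of Emp1 (-1.12), Stab1, a scavenger receptor (-0.75), Cd300c2 (-0.74), Tmem37 (-0.72), Vcan, a matrix proteoglycan (-0.71), and Cd93 (-0.70). Each of these genes was higher at 16 than at 4 hours in medium, and all but Emp1 were also higher at 16 hours with IFN-γ. They thus rose less with IFN-γ, or not at all. Whichever array was left out, Cxcl9, Iigp1, Gbp2, Cnn3, Igtp and Ccl9 were called. The total was 14 when any 1 of the 4 arrays at 4 hours was left out, 17 without array 1 and 10 without array 2 of medium at 16 hours, and 7 in a fit of the 4 arrays compared. Wars differed by 0.64 on its brightest probe set (adjusted p = 0.0922, or 0.0155 with the block). The next rose by 1.26 (adjusted p = 0.0177) and the dimmest differed by 0.55 (adjusted p = 0.149).

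The response at both times overlapped. Of the 32 probe sets that rose at 4 hours, 16 also rose at 16 hours. The comparisons share no arrays except through the estimate of spread, which pools all 8. Of the 32, 27 were higher with IFN-γ at 16 hours, and all 12 that fell at 16 hours were lower at 4 hours. The additive fit of time and treatment over all 8 arrays called 45 probe sets higher and 21 lower with IFN-γ, or 88 and 69 with the replicate number as a block. Its total of 66 was 38 and 36 without array 1 or 2 of medium at 4 hours, 38 without array 1 of medium at 16 hours, and 36 and 39 without IFN-γ array 1 or 2 at 4 hours.

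Whether the effect of IFN-γ differed between the times was tested directly. Cxcl10 differed between IFN-γ and medium by 2.35 at 4 hours and by 0.88 at 16 hours (adjusted p = 0.0886, or 0.0049 with the block), and the effects differed by -1.47 (SE 0.22). The effects on Ccl9, -0.53 at 4 hours (adjusted p = 0.15, or 0.0266 with the block) and -1.83 at 16 hours, differed by -1.30 (SE 0.15). Limma called 0 probe sets over all 12422, with a smallest adjusted p of 0.158, and 353 had an unadjusted p under 0.05. The fit with the replicate number as a block called 30, all with a negative difference, 16 minus 4 hours. Among them were Cxcl10 (adjusted p = 0.00948), whose rise was smaller at 16 hours, and Ccl9 (adjusted p = 0.00852), whose fall was larger. The type I interferon-stimulated genes had a median difference of -0.34, with 0 of 18 called (0 adjusted over the list alone), a camera adjusted p = 2.29e-12, and adjusted p = 0.355 with an estimated correlation. For Ifit2 and Adar, though not for Isg15, a rise with time in medium enters this difference.

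Between 4 and 16 hours in medium alone, macrophage markers rose, the C1q genes among them, and genes of costimulation and maturation fell. C1qa, C1qb and C1qc, which encode the chains of complement component C1q, rose by 1.94 (SE 0.11, adjusted p = 0.000177), 2.06 (SE 0.14) and 1.73 (SE 0.11). The Fc receptor gene Fcgr1 rose by 2.08 (SE 0.16, adjusted p = 0.000362), Ccl2, a monocyte chemokine, by 1.63, and Lyz2, which encodes lysozyme, by 1.61. Gzmb, which encodes granzyme B, fell by 2.02 (SE 0.13, adjusted p = 0.000178), from 8.81 ± 0.00 to 6.79 ± 0.20. Fscn1, the actin-bundling protein of mature dendritic cells, fell by 1.46 (SE 0.10, adjusted p = 0.000245), Cd40 fell by 1.16 (SE 0.13, adjusted p = 0.00217), and Il1rn, the interleukin 1 receptor antagonist, fell by 1.64.

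Of 22 measured genes of costimulation and maturation, 12 fell and none rose (15 fell and 1 rose adjusted over the list alone, and with the block), among them Ccl22 (-1.44), Fscn1, Cd40 and Traf1 (-0.78). The camera adjusted p was 3.02e-11, and adjusted p = 0.0766 with an estimated correlation. Of 12 macrophage markers, 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a camera adjusted p = 1.07e-10 and adjusted p = 0.0546 with an estimated correlation. The one that fell was Spic, a transcription factor of red pulp macrophages (6.30 ± 0.03 to 5.28 ± 0.32), and Cd68 rose by 1.21. Of 18 pattern recognition and uptake receptors 7 rose (9 up and 1 down adjusted over the list alone, and with the block), among them Msr1 (1.09) and Clec4a2 (1.08), with a camera adjusted p = 4.53e-06 and adjusted p = 0.255 with an estimated correlation. Of 32 cell cycle genes 9 fell (13 adjusted over the list alone, and 14 with the block), including Mcm5 (-0.85), Mcm2 (-0.67) and Mcm7 (-0.68), subunits of the replicative helicase, with a camera adjusted p = 1.25e-08 and adjusted p = 0.0848 with an estimated correlation. Of 15 genes of cholesterol synthesis and uptake 2 fell (5 adjusted over the list alone, and 7 with the block), Fdps (-1.06) and Idi1 (-1.05), with a camera adjusted p = 0.000142 and adjusted p = 0.0848 with an estimated correlation. Of 24 immediate early and heat shock genes, a group that also moves with handling, 7 fell and 1 rose (10 and 2 adjusted over the list alone, and 9 and 2 with the block), with Hspa1b at -1.26, a camera adjusted p = 4.58e-05, and adjusted p = 0.314 with an estimated correlation.

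In medium, 212 probe sets rose and 319 fell with time, and the fit with the replicate number as a block called 562 and 1005. On the list of MHC class II presentation 3 of 17 genes rose (8 up and 1 down adjusted over the list alone, and 7 and 1 with the block; camera adjusted p = 0.000516, and adjusted p = 0.43 with an estimated correlation), all of them lysosomal proteases, with Ctsl at 1.45, Ctsd at 1.05 and Ctsb at 0.77, and so did Tyrobp (0.92, adjusted p = 0.00442). Hbb-b2, a globin gene, fell by 1.67, Mt1, a metallothionein, fell by 1.56, and Laptm4b fell by 1.53. The total of 531 was 73 and 85 without array 1 or 2 of medium at 4 hours, 176 and 206 without array 1 or 2 of medium at 16 hours, 264 without either IFN-γ array at 4 hours, and 923 without either IFN-γ array at 16 hours. The balance depended on the setting: 252 rose and 257 fell with quantile normalization, 177 and 378 with median centring, and 317 and 291 without both 16-hour arrays of number 1. Rises outnumbered falls without array 1 of medium at 16 hours (116 and 60) and without array 1 (46 and 27) or array 2 (51 and 34) of medium at 4 hours, and 131 rose and 133 fell without either IFN-γ array at 4 hours. The Actb ratio was 2.04 and 2.20 at 4 hours and 1.63 and 1.57 at 16 hours, and 1 of 14 B cell markers rose with time (2 adjusted over the list alone, and 4 with the block). The median of the B cell markers was 0.24, with a camera adjusted p = 0.000516 and adjusted p = 0.314 with an estimated correlation.

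**Figure D2:**
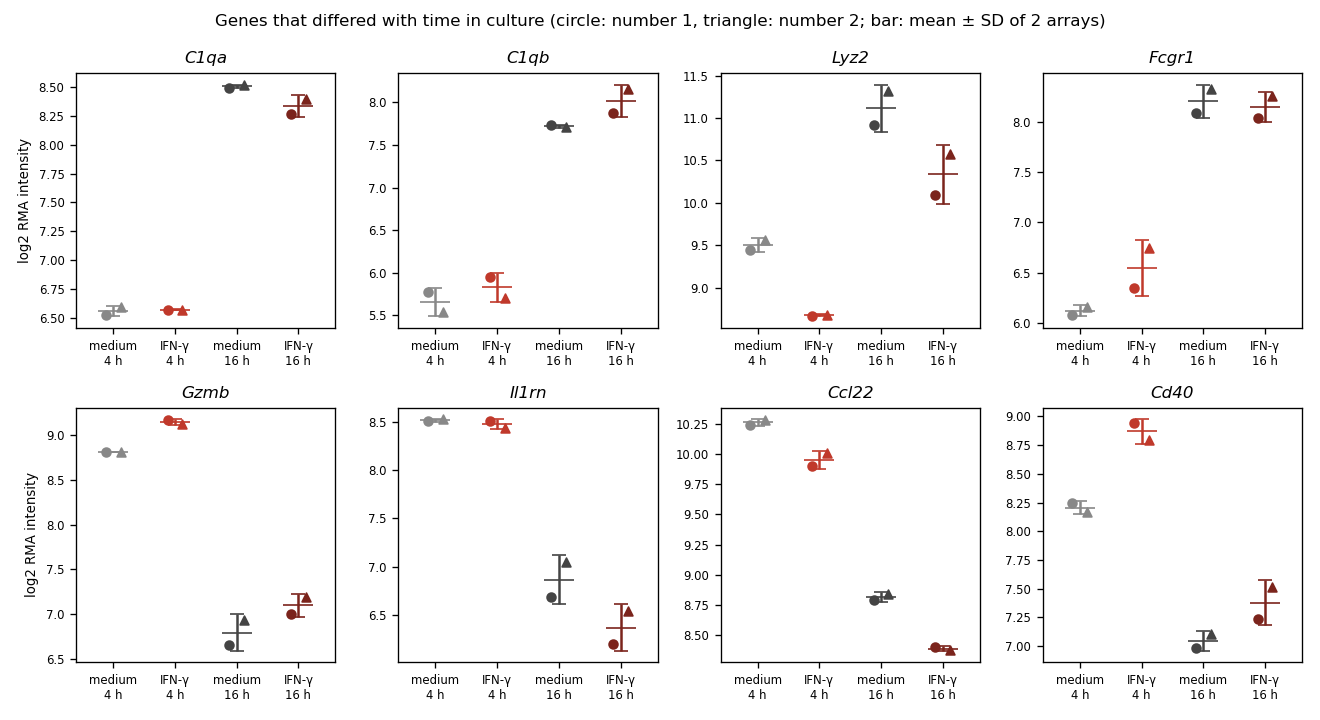
Log2 RMA intensity (vertical axis, a separate range for each gene) of 8 genes in the 4 groups, with a point per array, a bar at the mean and whiskers of 1 SD (n = 2). C1qa read 6.56 and 8.50 in medium at 4 and 16 hours, and 6.58 and 8.33 with IFN-γ, while Gzmb read 8.81 and 6.79 in medium and 9.15 and 7.09 with IFN-γ.

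With IFN-γ, the same C1q genes rose between 4 and 16 hours and Gzmb fell. C1qb, C1qc and C1qa rose by 2.18, 1.77 and 1.76 (adjusted p = 0.000208, 0.000206 and 0.000206), Lyz2 by 1.66, Fcgr1 by 1.60 and Pla2g7, a lipoprotein-associated phospholipase, by 1.52. Il1rn fell by 2.10 (SE 0.15, adjusted p = 0.000343) and Gzmb by 2.05 (-2.05, SE 0.13, adjusted p = 0.000206). Cxcl10, Ccl22, Cd40 and Cxcl9 fell as well, with log2 differences of -1.58, -1.56, -1.49 and -1.48. Of 22 genes of costimulation and maturation 13 fell (17 adjusted over the list alone), with a camera adjusted p = 3.87e-18 and adjusted p = 0.0469 with an estimated correlation. Of 12 macrophage markers 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a camera adjusted p = 2.94e-08 and adjusted p = 0.0469 with an estimated correlation.

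In all, 102 probe sets rose and 161 fell with time in IFN-γ, or 397 and 862 with the replicate number as a block. Of 14 B cell markers 2 rose (12 adjusted over the list alone, and 10 with the block), with a camera adjusted p = 9.37e-09 and adjusted p = 0.0919 with an estimated correlation. The total of 263 was 117 without either array of medium at 4 hours, 31 and 27 without IFN-γ array 1 or 2 at 4 hours, and 120 in a fit of the 4 arrays compared. The balance turned to 106 rises and 70 falls without IFN-γ array 1 at 16 hours and to 171 and 107 without both 16-hour arrays of number 1, and it was 149 and 559, or 708 in all, without IFN-γ array 2 at 16 hours. On the 2 IFN-γ arrays at 4 hours the Actb ratio was 1.47 and 1.65, and at 16 hours it was 1.68 and 1.66.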

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

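The tests of the first pattern and of the costimulation and macrophage pattern, and the count of other splits, were chosen after the results they bear on had been seen; the test on arrays of the other number was written before its result.

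Of 31 genes named at 4 or 16 hours, 11 had a difference between the effects of IFN-γ at the times with an adjusted p under 0.05 (limma, Benjamini-Hochberg over these genes alone). For 10 of the 11 the difference was negative, through a smaller rise or a larger fall at 16 hours. All 31 genes were named for the size of a called effect at 1 of the times, which enters the difference itself. The adjustment over them alone therefore overstates the evidence that the effects differ. The difference (16 minus 4 hours, log2) was -1.47 for Cxcl10, -0.93 for Ubd, -0.78 for Irgm2, -1.13 for Ikzf1 and -0.85 for Mxd1, all genes whose rise was smaller or absent at 16 hours. It was -1.30 for Ccl9, -0.79 for Emp1, -0.59 for C3ar1, -0.70 for Tmem37 and -0.58 for Vcan, all genes whose fall was larger at 16 hours. Each of these was also higher in medium at 16 than at 4 hours. At 4 hours C3ar1 and Vcan were below the antisense controls and Tmem37 was at their level, which limits the fall that could be read then. The difference was 0.59 for Il18bp, the 1 gene with a positive difference, whose rise was larger at 16 hours. None of these passed over all 12422 probe sets by limma without the block, where 353 had an unadjusted p under 0.05, and 4 of the 11 passed with the block: Cxcl10, Ccl9, Ikzf1 and Emp1.

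By camera, 7 lists differed between the times, none with an estimated correlation. The median difference was -0.17 for interferon-inducible GTPases, -0.34 for type I interferon-stimulated genes, -0.11 for costimulation and maturation, and -0.17 for cytokines and chemokines. It was -0.13 for pattern recognition and uptake receptors, 0.11 for B cell markers and -0.17 for macrophage markers.

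With the replicate block, 100 probe sets rose with IFN-γ at 4 hours and were not called higher at 16 hours, with a median of 0.63 at 4 and -0.07 at 16 hours. An induction that passes in IFN-γ cells alone, with medium level over time, is argued against as the whole cause. In medium the same probe sets were a median 0.50 higher at 16 than at 4 hours, or 0.794 of the rise (bootstrap interval 0.539 to 0.916). Bootstrap intervals in this paragraph resample probe sets or genes, not arrays. The choice of these probe sets sets a gap between the changes with time in medium and in IFN-γ. Only the division of this gap between medium and IFN-γ is informative. Probe sets chosen on arrays of 1 number gave shares of 1.0 and 0.741 on the other. Noise of the single arrays used for the choice thus does not account for the rise in medium. Both parts of each share hold the medium arrays at 4 hours, so a deviation common to these arrays is not excluded. With IFN-γ the 100 probe sets changed by a median of -0.20 from 4 to 16 hours. Those chosen on arrays of 1 number changed by -0.04 and -0.23 on the other. A passing induction would give such a fall, so it is not excluded for a part of the pattern. For 35 genes of the 100 probe sets, Ido1 with its dimmer probe set among them, other probe sets brighter than the median showed 0.161 of the rise (-0.0084 to 0.268). The share was 0.595 for rises with time in IFN-γ, where no array of medium at 4 hours enters. The median probe set lies at the level of the antisense controls, so some of the other probe sets, that of Ido1 among them, may show no rise for lack of signal. The share alone therefore cannot tell lower 5' signal from weak probe sets. Lower signal toward the 5' end on the arrays of medium at 4 hours, where the Actb ratios were 2.04 and 2.20, stays a candidate explanation. An earlier start in IFN-γ of a rise that medium also shows stays open as well.

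Macrophage genes were higher and costimulation genes lower at 16 than at 4 hours in medium. A lower share of dendritic cells would raise the markers of every other type alike, if those types kept their proportions. In that form it is argued against as the whole cause. Macrophage markers moved by a median 0.80 more than the markers of T, NK and B cells and neutrophils. The bootstrap interval was 0.2 to 1.38, which excludes 0 but not the bound of 0.3 first set. Bootstrap intervals in this paragraph resample genes on the same arrays, so they hold no spread between arrays or cultures. Among genes of the fixed set, Cd8a, Itgax and Irf8, markers of the sorted cell, differed by -0.05, -0.05 and -0.47 with time in medium. Other markers of this cell moved either way. For lower 5' signal in medium at 4 hours, the change of all 12 macrophage markers in IFN-γ was 0.766 of that in medium (0.265 to 1.24), which leaves it open, while a test added after that, on the 8 called markers, gave 0.999 (0.608 to 1.24) and argues against it as their whole cause. A larger share of macrophages may also account for these rises (Lyz2 read 9.51 and 11.12 at 4 and 16 hours) and was not excluded. No measure of the purity of the cells was used here.

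Genes that rose with time in medium tended to be lower with IFN-γ at 16 hours, which the shared arrays of medium at 16 hours could produce. The 200 genes with the largest rise on arrays of 1 number had, on arrays of the other number, median IFN-γ differences of -0.139 and -0.185, below the lowest 2.5% of 10000 random lists of like mean intensity (-0.0394 and -0.0196). Noise of a single shared array is thus argued against as the whole cause. A deviation common to both arrays of medium at 16 hours would pass this test and is not excluded. Genes of the random lists need not move together, which may make these limits too narrow. That IFN-γ holds back part of the change seen in medium is a hypothesis, since it was found on these arrays.

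For the additive fit over both times, 2 of 34 splits of the 8 arrays gave as many calls, the real one with 66 and the highest other with 1743. That other split follows the replicate number, which points to a structure of the arrays by number, and every remaining split gave 0. The share of splits alone does not exclude chance. Among the 8 splits that part all 4 pairs of arrays of the same time and number, the real split gave 66 and the highest other 0, and 8 splits are too few for a share under 0.05. With the replicate block the additive fit called 157.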

How the results depend on the processing

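The fit without both 16-hour arrays of number 1 and the one without probe sets low in medium at 4 hours were chosen after the results were seen; the other alternatives were planned. Of the values of named genes under alternatives other than a left-out array, 1308 kept their side of the threshold, 104 lost a call, 22 gained one and 0 called values turned; with an array left out the counts were 873, 175, 8 and 0. Over the named genes, Ido1 included, 56 values that were not called changed sign. For gene lists, 84 kept and 81 lost the call under other settings, and 379 and 59 with an array left out. For the interferon-inducible GTPases, camera's direction turned in 2 results without IFN-γ array 1 at 16 hours. For the difference of effects the median was then 0.0855 (adjusted p = 0.872), in a range of -0.49 to 0.0855 with an array left out. For time in IFN-γ the median was then -0.0529 (adjusted p = 0.62), still negative, in a range of -0.493 to -0.0529. The cause was not tested.

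With the replicate block, limma called 157 probe sets at 4 hours, 105 at 16 hours, 30 for the difference of effects, 1567 for time in medium, 1259 for time in IFN-γ and 157 over both times. In fits of only the 4 arrays compared, which use fewer arrays, it called 93 at 4 hours, 7 at 16 hours and 120 for time in IFN-γ. At an adjusted p under 0.01 the counts were 14, 9, 144, 66 and 35 for 4 hours, 16 hours, time in medium, time in IFN-γ and both times, and with a log2 difference of at least 1 they were 18, 17, 94, 64 and 20, both stricter by construction. With 1 mean value per gene the 4-hour count was 20. Leaving out both 16-hour arrays of number 1 makes the 4-hour comparison the same fit as that of the 4 arrays compared, so it gives no separate count. Leaving out the probe sets low in medium at 4 hours removes 4-hour rises by construction and gave 24 at 4 hours. With an array left out, the counts ran from 8 to 67 at 4 hours, 10 to 38 at 16 hours, 73 to 923 for time in medium, 27 to 708 for time in IFN-γ and 36 to 77 over both times. Where not stated, the cause was not tested.

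Gene lists called fell from 15 to 0 at 4 hours, 9 to 0 at 16 hours, 7 to 0 for the difference of effects, 10 to 0 for time in medium and 14 to 2 for time in IFN-γ with an estimated correlation. Fry called 5, 3 and 0 lists for 4 hours, 16 hours and the difference. With an array left out, 9 to 15 lists were called at 4 hours and 4 to 10 for the difference.

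The dimmer probe set of Ido1 passed at 4 hours under quantile normalization (0.707, adjusted p = 0.0201) and median centring (0.707, adjusted p = 0.0415). It also passed with the replicate block (0.712, adjusted p = 0.00511) and with the 4 arrays alone (0.712, adjusted p = 0.0184). Without both 16-hour arrays of number 1 the 4-hour comparison is the same fit as with the 4 arrays alone, so it adds no separate result. With an array left out the difference of this probe set ran from 0.693 to 0.731. It was not among the probe sets kept when the dimmest 40% were left out, so that alternative gave no value.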

Other observations

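No test in this part was chosen after its result was seen.

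Further lists differed with IFN-γ by camera with the preset correlation, none with an estimated one. At 4 hours, 2 of 30 cytokine and chemokine genes rose, Cxcl9 and Cxcl10 (2 up and 1 down adjusted over the list alone, and with the block; camera adjusted p = 0.000503, and adjusted p = 0.0819 with an estimated correlation). At 4 hours, 1 of 24 JAK-STAT receptors and regulators rose, Socs1 (camera adjusted p = 0.008, and adjusted p = 0.211 with an estimated correlation). None of 17 genes of MHC class II presentation and none of 12 of DAP12 and ITAM signalling passed by limma (0 and 1 with the block), and their medians at 4 hours were -0.09 and -0.16 (camera adjusted p = 0.0144 for both, and adjusted p = 0.418 and 0.31 with an estimated correlation). At 16 hours, none of 32 cell cycle genes and none of 14 glycolysis genes passed by limma, and their medians were 0.12 and 0.10 (camera adjusted p = 5.49e-05 and 0.00464, and adjusted p = 0.189 and 0.408 with an estimated correlation).

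Markers of other cell types were measured as well. At 4 hours with IFN-γ, none of 14 B cell markers and none of 13 neutrophil and monocyte markers passed by limma, and their medians were -0.13 and -0.16 (camera adjusted p = 2.71e-05 and 0.000551, and adjusted p = 0.196 and 0.211 with an estimated correlation). Between 4 and 16 hours in medium the medians of T cell, NK cell, B cell, neutrophil and macrophage markers were 0.02, -0.03, 0.24, -0.13 and 0.92. The markers of CD8+ dendritic cells had a median of 0.01 at 4 hours (camera adjusted p = 0.738) and -0.05 at 16 hours (camera adjusted p = 0.606) with IFN-γ. Genes of oxidative phosphorylation and of cytosolic ribosomal proteins had medians of 0.01 and 0.01 at 4 hours (camera adjusted p = 0.902 and 0.787).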
